A study of Mus musculus with 15 samples.

How the data were processed

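PolyA RNA of ILC2 and ILC3 sorted from mouse small intestine was sequenced in 15 libraries over 4 times of day. Per the labels' protocols, the intestines of 6 mice per time were digested, the cells were pooled, stained with antibodies and sorted by flow cytometry, RNA was taken with an RNeasy Micro kit, and libraries were made with a TruSeq RNA kit from 100 ng of total RNA. The antibodies and gates of the sort were not given in the sources used here. The authors deposited 1 file per library with raw read counts per gene, under NCBI Entrez gene identifiers with gene lengths, and the values were whole numbers without normalization. Reads were counted with featureCounts on the mm10 genome build, per the submitters' processing notes. The aligner, the strand setting and the treatment of reads that map to several places were not given in the sources used here.

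The files held 22797 genes, of which 22718 were named through the NCBI RefSeq gene table of GRCm38.p6, the same build as mm10; positions are 1-based from that table. Samples were grouped by the cell type and time in their labels, with the replicate number in the title; the label of the ILC2 ZT16 library carries no number. Total counts ranged from 4016298 to 18538315 in ILC2 and from 5903163 to 24794403 in ILC3. Replicates were compared before averaging, and chi-square per degree of freedom between the 2 libraries of a group ran from 22.0 to 229, above the 1 of sampling noise; libraries of different groups were not compared in this way.

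Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 15339 genes. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood model of 8 group means over all 15 libraries, with 7 residual degrees of freedom (median prior 5.1). The common biological coefficient of variation was 0.425. The fit shares its spread between groups because 1 group holds 1 library. Tests were the mean of the ILC3 groups minus the mean of the ILC2 groups, F-tests over the 4 times in each cell type, the F-test of the interaction, and ZT16 minus ZT4 and ZT23 minus ZT10 in each cell type. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Log2 fold changes were the fitted values of this model with edgeR's default prior count, and their standard errors came from the same fit. CPM values were scaled with TMM factors. Where a group had 0 counts the fold was computed against 3 counts over the group, and for 1 to 14 counts ratios of summed counts have exact 95% intervals; intervals and floors cover counting error only, since reads carried no molecular identifiers.

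Before the data were examined, 26 gene lists (647 symbols, 642 found), the tests, the alternatives and the rule for named genes were fixed. The lists were the core clock, clock output, ILC2 signature, ILC3 signature, cytotoxic and type 1 lymphocytes, T cells, B and plasma cells, myeloid with dendritic and mast cells, epithelium, stroma and endothelium, erythroid, immediate-early, heat shock, glucocorticoid response, proliferation, oxidative phosphorylation, glycolysis, cholesterol, lipid uptake, unfolded protein response, interferon response, class II presentation, NF-kB and TNF signalling, homing, receptors for neural, hormonal and metabolic signals, and ribosomal proteins. For each list the members passing were counted over all genes and adjusted over the list alone, and limma 3.58.1 camera with a preset correlation of 0.01 was run on voom values, with an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry tests whether a list's genes move on balance one way. Medians of fitted values were also taken with genes at 0 counts held at their bound, and the text gives both where they differ.

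Named genes for cell type were the 10 with the largest fold change in each direction among those with adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 10 CPM in the higher cell type and no overlap between the 7 ILC2 and 8 ILC3 libraries; 556 genes higher in ILC3 and 471 higher in ILC2 met these criteria. Clock genes, the fixed sort markers and up to 4 members of each list with the smallest p were also named; genes over all tests of time were to be named at adjusted p under 0.05, and none reached it in edgeR. Predicted genes, microRNA, small nucleolar RNA and mitochondrial genes were skipped in naming. Some genes that these rules choose are not analysed here by name, though the counts of lists and calls hold them. Other members of a list are examples chosen after their values were seen. Peak times came from a least squares cosinor with a period of 24 hours on log2 CPM, as a description without a test.

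The same pipeline was tested on simulated counts drawn from the means, library sizes and dispersions of these data with 200 changed genes. For cell type it called 45% of 2-fold and 75% of 4-fold changes, with 11 false calls among 131. For time in ILC3 it called 2% and 39%, for time in ILC2 1% and 31%, and for the interaction 0% and 0%. For ZT23 minus ZT10 it called 2% and 38% in ILC3 and 0% and 39% in ILC2, and for ZT16 minus ZT4 1% and 38% in ILC3 and 0% and 2% in ILC2.

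The alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library size only, no low-count filter, a mean of at least 5 CPM, an adjusted p under 0.01, glmTreat against an absolute log2 fold change of 0.5 for time and 1 for cell type, only the libraries of the cell type tested, a cosinor in place of 4 free means, a replicate block, the time of 22 hours in place of 23, cell type without the ZT16 groups, and each library left out in turn. After seeing the data, voom with sample quality weights, a fit without 3 libraries that stood apart (ILC2 ZT4 replicate 1, ILC3 ZT4 replicate 1 and ILC3 ZT23 replicate 2), Jchain as a covariate within each cell type, and lists of markers of plasma cells, plasmacytoid dendritic cells, mature B cells and macrophages were added. Batch could not be a term because it equals cell type. Reads and sequence were not used here.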

Results

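Gene expression was measured by RNA sequencing in group 2 and group 3 innate lymphoid cells (ILC2 and ILC3), lymphocytes without rearranged antigen receptors, from the small intestine of female mice. Cells were taken at zeitgeber times 4, 10, 16 and 23 (ZT4, ZT10, ZT16 and ZT23; hours counted from the cue that sets the animals' day). The 15 libraries formed 8 groups of 1 cell type at 1 time, with 2 libraries in each group except ILC2 at ZT16, which had 1 library and no replicate check of its own. Total counts of the ILC2 libraries, in units of 1e+06, were 6.54 and 13.1 at ZT4, 4.02 and 18.5 at ZT10, 13.7 at ZT16, and 9.93 and 17.7 at ZT23. In the same units the ILC3 libraries had 5.9 and 21 at ZT4, 23.6 and 24.8 at ZT10, 20 and 18.5 at ZT16, and 20.6 and 15.2 at ZT23. The labels placed every ILC2 library in batch 1 and every ILC3 library in batch 2, so batch and cell type cannot be told apart, whereas times within a cell type were compared within a batch. Cells of 6 mice were pooled per time before the sort. The sources used here call the replicates biological but do not say whether the 2 libraries of a group came from separate pools, so p-values may measure only the spread between these samples, which may be technical.

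The first comparison asked which genes separate ILC3 from ILC2 over the day, as the mean of the 4 ILC3 times minus the mean of the 4 ILC2 times. Gata3, which ILC2 depend on, averaged 506 ± 140 CPM (counts scaled to 1e+06 per library, SD, n = 7) in ILC2 and 35.1 ± 11.9 (n = 8) in ILC3, a log2 fold change of -3.85 ± 0.25 (SE; adjusted p = 1.03e-06). The type 2 cytokine genes Il5 (-6.36 ± 0.48) and Il13 (-5.15 ± 0.46), the alarmin receptor gene Il1rl1 (-3.41 ± 0.20), the inhibitory receptor gene Klrg1 (-5.81 ± 0.27) and the repair factor gene Areg (-2.79 ± 0.29) were higher in ILC2. The cytokine gene Il22 (5.66 ± 0.65), the cytokine receptor gene Il23r (5.10 ± 0.37), the chemokine receptor gene Ccr6 (5.29 ± 0.26) and the activating receptor gene Ncr1 (3.49 ± 0.38) were higher in ILC3. Il17a, a cytokine gene fixed as an ILC3 marker, averaged 8.21 ± 6.22 CPM in ILC2 and 6.77 ± 3.13 in ILC3 and was not called (-0.19 ± 0.43, adjusted p = 0.808).

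The genes with the largest fold changes and no overlap between libraries went beyond these markers. Highest above ILC2 in ILC3 was Il22ra2 (Entrez 237310; mm10 chromosome 10, 19622028 to 19634681), which encodes the soluble receptor that binds and blocks interleukin-22. It had 6 counts over the 7 ILC2 libraries and 125 ± 79.2 CPM in ILC3 (ratio of counts 1376, interval 632.2 to 3751, fitted log2 fold change 11.90 ± 0.84, adjusted p = 5.52e-06). Gp2 (Entrez 67133; chromosome 7, 119442537 to 119459272), a receptor for bacterial pili best known from M cells, had 3 counts in ILC2 and 42.3 ± 25.3 CPM in ILC3, a ratio of 1002 with a 95% counting interval of 342.6 to 4859. The granulocyte and mast cell protease genes Mcpt8 and Cma1 had 2 and 0 counts in ILC2 and averaged 23.1 ± 10.6 and 10.6 ± 5.82 CPM in ILC3. The ratio for Mcpt8 was 912.7 with an interval of 252.5 to 7539, and Cma1 was at least 261.7-fold higher against a floor of 3 counts over the ILC2 group, or at least 212.6-fold by the exact 95% interval. The calcium channel gene Cacna1g (14 counts in ILC2, ratio 433.9, interval 258.5 to 793.9) and the adhesion molecule gene Dscam (4 counts, ratio 427.3, interval 166.7 to 1569) were also higher in ILC3. The signalling genes Grb10 (2 counts in ILC2; ratio 794, interval 219.6 to 6559) and Mapk10 (2 counts; ratio 569.5, interval 157.5 to 4705), the lectin-like receptor gene Klra5 (8 counts; ratio 173.1, interval 87.71 to 401.3) and the meiosis gene Mei1 (5 counts; ratio 178.3, interval 76.25 to 549.7) completed the set.

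Highest above ILC3 in ILC2 was Dntt (Entrez 21673; chromosome 19, 41029275 to 41059525), the template-free DNA polymerase of lymphoid precursors, at 34.9 ± 17.5 CPM in ILC2 and 0.072 ± 0.0699 in ILC3 (-8.63 ± 0.62, adjusted p = 1.96e-06). The surface antigen gene Ly6a (Entrez 110454; chromosome 15, 74994877 to 74998031) averaged 670.4 ± 204 CPM in ILC2 and 4.71 ± 3.06 in ILC3 (-7.18 ± 0.40, adjusted p = 3.2e-07). Siglech, a lectin gene of plasmacytoid dendritic cells, averaged 298 ± 102 and 2.38 ± 1.22 CPM (-7.06 ± 0.41). Across the 7 ILC2 libraries Dntt had a Pearson's r of 0.931 with Siglech. Which cells the Dntt RNA came from was not tested. The retinoid receptor gene Rxrg (-6.90 ± 0.46), the chemokine receptor gene Ccr4 (-6.57 ± 0.30) and the costimulatory ligand gene Cd40lg (-6.59 ± 0.60) were higher in ILC2, as was Il5. The granule protein genes Prg2 (-6.50 ± 0.55) and Rnase2b (-6.32 ± 0.70), both known from eosinophils, were also higher in ILC2. Prg2 and Ly6a were highest in ILC2 ZT23 replicate 1 (471 and 1071 CPM) and lowest in replicate 2 (30.4 and 416 CPM), as was Jchain, the joining chain gene of plasma cells (188360 and 18105 CPM), and Rnase2b was also lowest in replicate 2 (1.66 CPM). Gata3 and Ccr4 were lowest in replicate 1, at 302 and 187 CPM. Pearson's r with Jchain across the ILC2 libraries was 0.981 for Prg2, 0.903 for Ly6a and 0.799 for Rnase2b. It was -0.805 for Gata3 and -0.909 for Ccr4. Which cells the RNA of Prg2, Ly6a and Rnase2b came from was not tested. Reads shared between near-identical copies can be split or dropped in ways the sources used here do not give, so values of family members such as Klra5, Rnase2b, the mast cell proteases and the hemoglobin genes are uncertain.

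**Figure D1:**
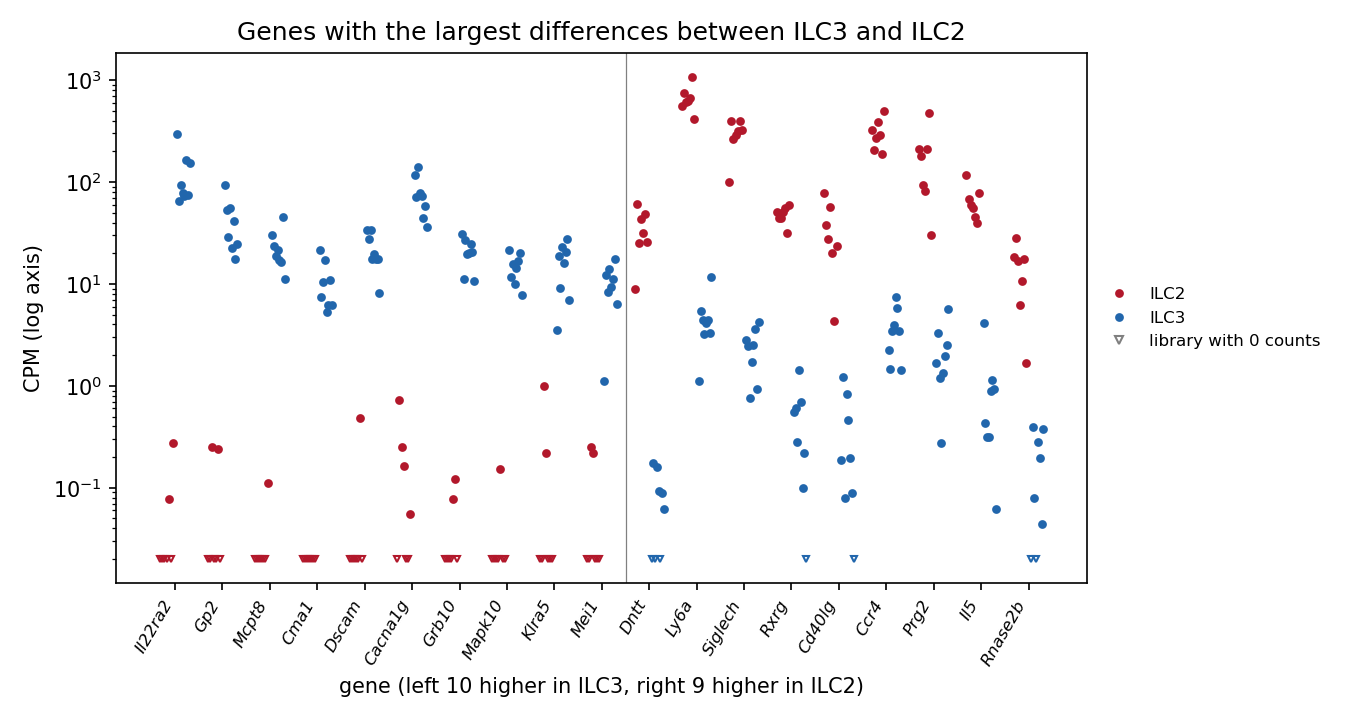
CPM on a log axis of the 10 genes with the largest fold change towards ILC3 and 9 of the 10 towards ILC2, with each point 1 of the 7 ILC2 (red) or 8 ILC3 (blue) libraries and open triangles marking libraries with 0 counts. The libraries of the cell types did not overlap for any gene shown, and Ly6a lay between 416 and 1071 CPM in ILC2 and between 1.12 and 11.6 CPM in ILC3.

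Among the gene groups, 24 of 28 ILC2 signature genes were lower in ILC3 than in ILC2, and 25 adjusted over the list alone (median log2 fold change -3.63, camera adjusted p = 1.04e-24, adjusted p = 0.238 with an estimated correlation). The receptor genes Il17rb (-6.27 ± 0.28) and Ptgir (-6.00 ± 0.26) and the sulfotransferase gene Hs3st1 (-5.57 ± 0.22) led it. Of 30 ILC3 signature genes 19 were higher and 2, the cytokine genes Csf2 (-2.97 ± 0.20) and Lif, were lower, with 22 adjusted over the list alone (median 1.65, camera adjusted p = 7.17e-07, adjusted p = 0.382 with an estimated correlation). All 11 genes of antigen presentation on class II molecules were tested, and 9 were higher in ILC3, 9 adjusted over the list alone (median 1.99, camera adjusted p = 2.1e-06, adjusted p = 0.382 with an estimated correlation). H2-DMb2 (3.21 ± 0.25), the master regulator gene Ciita (2.48 ± 0.32) and H2-Aa (2.01 ± 0.30) were among them. Genes of cell division were higher in ILC3 for 12 of 30 members, 18 adjusted over the list alone, with Mcm5 at 1.18 ± 0.16 and Ccnb2 at 1.79 ± 0.32 (median 0.87, camera adjusted p = 7.71e-06, adjusted p = 0.538 with an estimated correlation). The count of 12 became 20 without ILC2 ZT4 replicate 2 or ILC3 ZT23 replicate 1, and the count of 18 became 11 without ILC3 ZT10 replicate 1 or ILC3 ZT16 replicate 2.

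Receptors that place cells or receive neural and hormonal signals also differed. Of 27 homing genes 12 were lower and 6 higher in ILC3, and 20 passed adjusted over the list alone (median -0.48, camera adjusted p = 0.0216, adjusted p = 0.583 with an estimated correlation). The camera call was lost without ILC3 ZT4 replicate 2 (adjusted p = 0.137). The chemokine receptor genes Ccr8 (-5.53 ± 0.23) and Ccr4 were higher in ILC2, whereas Ccr6 was higher in ILC3. Of 27 receptor genes for neuropeptides, hormones and metabolites, 9 were lower and 4 higher in ILC3, 13 adjusted over the list alone. The neuromedin U receptor gene Nmur1 (-4.53 ± 0.30; 160 ± 50.6 CPM in ILC2, 7.54 ± 4.18 in ILC3) was higher in ILC2. As a list these receptors passed camera as lower in ILC3 (adjusted p = 0.0216; adjusted p = 0.606 with an estimated correlation), but their median of -0.10 became 0.03 with library size as the only scaling. The call was lost without ILC2 ZT23 replicate 2 (adjusted p = 0.083) or ILC3 ZT23 replicate 2 (adjusted p = 0.0677).

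Genes of the unfolded protein response, which handle protein load in the endoplasmic reticulum, were lower in ILC3 for 18 of 23 members, 19 adjusted over the list alone (median -0.92, camera adjusted p = 3.13e-10, adjusted p = 0.382 with an estimated correlation). Xbp1 averaged 2109 ± 1202 CPM in ILC2 and 219 ± 41 in ILC3 (-3.30 ± 0.33), and Pdia4 was at -1.73 ± 0.19. Across the 7 ILC2 libraries the list had a median Pearson's r of 0.804 with Jchain (rho 0.75, exact permutation p = 0.00734, Benjamini-Hochberg p over 60 relations 0.0997). Xbp1 had an r of 0.963. How much of the list's difference comes with plasma cell RNA was not tested. B cell and plasma cell genes moved with the unfolded protein response genes. In that list 9 of 15 were lower in ILC3, 10 adjusted over the list alone, among them Mzb1 (-5.39 ± 0.45), Tnfrsf17 (-5.30 ± 0.42) and Jchain (-6.13 ± 0.54) (median -2.65, camera adjusted p = 1.77e-08, adjusted p = 0.238 with an estimated correlation). Jchain, which encodes the joining chain of secreted antibodies, took 1.85% to 15.7% of all counts in the ILC2 libraries and 0.0275% to 0.43% in the ILC3 libraries. Interferon-response genes were lower in ILC3 for 18 of 30 members and higher for 2, with 21 adjusted over the list alone (median -0.75, camera adjusted p = 2.34e-06, adjusted p = 0.382 with an estimated correlation), including Oas3 (-1.97 ± 0.19), Isg20 (-2.04 ± 0.19) and Bst2 (-1.84 ± 0.22). Ribosomal protein genes were lower in ILC3 for 19 of 48 members and higher for 3, with 24 adjusted over the list alone (median -0.39, camera adjusted p = 1.96e-05, adjusted p = 0.751 with an estimated correlation). Cholesterol synthesis and uptake genes were lower for 7 of 24 and higher for 2, Idi1 (0.82 ± 0.16) and Pmvk, with 10 adjusted over the list alone (median -0.28, camera adjusted p = 0.00654, adjusted p = 0.419 with an estimated correlation). Cyp51 was at -1.18 ± 0.14.

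Markers of other cell types differed as well. Of 24 genes of cytotoxic and type 1 lymphocytes 12 were higher in ILC3 and 2 lower, with 17 adjusted over the list alone (median 2.22, camera adjusted p = 0.000234, adjusted p = 0.506 with an estimated correlation). The granzyme gene Gzma averaged 78.4 ± 26.1 CPM in ILC2 and 1660.5 ± 867 in ILC3, and the type 1 cytokine gene Ifng was lower in ILC3. Of 24 genes of myeloid cells, dendritic cells and mast cells 15 were higher in ILC3 and 2, Siglech and Ly6c2 (-5.41 ± 0.41), were lower, with 19 adjusted over the list alone (median 1.25, camera adjusted p = 4.51e-06, adjusted p = 0.239 with an estimated correlation). The mast cell gene Cpa3 was at 4.33 ± 0.37, and Mcpt1 averaged 895 ± 438 CPM in ILC3. T cell genes split, with 8 of 22 higher in ILC3 and 7 lower, 16 adjusted over the list alone. Cd28 (-4.46 ± 0.20), Cd6 (-3.53 ± 0.25) and Cd8b1 (-6.09 ± 0.40) were lower and Cd8a (2.22 ± 0.49) was higher, and the list did not pass camera, where its median was 0.11, its mean -0.28 and its test pointed down (adjusted p = 0.614). Epithelial genes had 1 of 28 called, Epcam (0.99 ± 0.31), and 0 adjusted over the list alone by edgeR (camera adjusted p = 0.14). Without ILC2 ZT4 replicate 2 the list had 10 called and 17 adjusted over the list alone, and without ILC3 ZT23 replicate 1 it had 2 and 1. Epcam was not called without any 1 of the other libraries except ILC2 ZT16 and ILC3 ZT4 replicate 1.

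The remaining lists did not pass camera for cell type. Core clock genes had 7 of 21 called, 8 adjusted over the list alone (camera adjusted p = 0.499). The repressor gene Nr1d1 averaged 26.7 ± 8.38 CPM in ILC2 and 154 ± 74.9 in ILC3 (2.62 ± 0.19), while Bhlhe41 (-5.10 ± 0.58) and Hlf (-2.47 ± 0.25) were higher in ILC2. Glycolysis had 11 of 20 called, 12 adjusted over the list alone, with Hk2 at 2.21 ± 0.26 (adjusted p = 0.254). Glucocorticoid-response genes had 10 of 17 and 10, 5 each way, with the receptor gene Nr3c1 at -1.67 ± 0.17 (median 0.08, mean -0.07, test down; adjusted p = 0.841). Genes of NF-kB signalling had 11 of 26 called, 11 adjusted over the list alone (adjusted p = 0.841). Immediate-early genes had 9 of 24 and 9 adjusted over the list alone (median -0.10, or 0.06 with library size as the only scaling, mean 0.08, test down; adjusted p = 0.841). Clock output genes had 7 of 26 and 7 (adjusted p = 0.632), and lipid uptake genes 6 of 26 and 6 (adjusted p = 0.461), led by the nuclear receptor gene Pparg at -4.56 ± 0.26. Stromal and endothelial genes had 6 of 16 and 6 (median 0.39, mean 0.83, test down; adjusted p = 0.841), or 3 and 3 without ILC2 ZT10 replicate 2 or ILC3 ZT23 replicate 2, and 3 and 4 without ILC3 ZT16 replicate 2. Heat shock genes had 3 of 16 and 3 (median 0.12, mean 0.15, test down, adjusted p = 0.952). The counts by edgeR were 0 of 43 for oxidative phosphorylation (adjusted p = 0.529) and 0 of 5 for erythroid genes (adjusted p = 0.632), each with 0 adjusted over the list alone. Without ILC3 ZT23 replicate 1, 3 erythroid genes were called (5 adjusted over the list alone), as were 5 genes of oxidative phosphorylation. Adjusted over the list alone, clock output had 3 without ILC3 ZT16 replicate 1, 4 without ILC2 ZT16 and 12 without ILC3 ZT4 replicate 2, and heat shock had 5 without ILC2 ZT23 replicate 1.

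**Figure D2:**
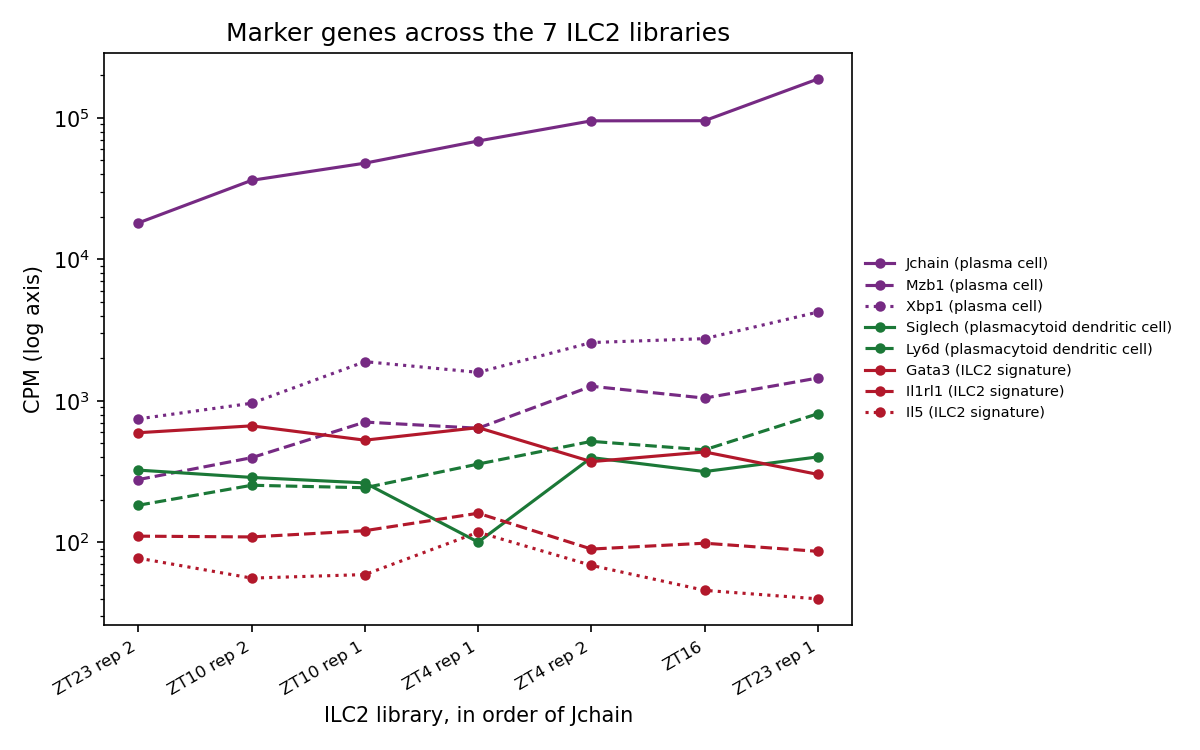
CPM on a log axis of plasma cell (purple), plasmacytoid dendritic cell (green) and ILC2 signature (red) genes, with each point 1 of the 7 ILC2 libraries in the order of their Jchain values. Jchain ran from 18105 to 188360 CPM, while Siglech was lowest, at 100 CPM, in ZT4 replicate 1, where Ly6d was at 357 CPM.

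By edgeR's quasi-likelihood test 4157 of 15339 genes differed between the cell types at adjusted p under 0.05, 2318 higher in ILC3 and 1839 higher in ILC2, and 5873 had an unadjusted p under 0.05. With library size as the only scaling the split was 2981 and 1315, and the median log2 fold change over all genes was 0.26 in place of 0.11. Of the 13 lists that passed camera, 0 passed with an estimated correlation and 13 passed limma's fry test, and 11 kept the call without each library in turn.

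The second question was which genes change over the day within a cell type. In ILC3, 4 of 21 core clock genes changed over the 4 times adjusted over the list alone: the activator genes Dbp (adjusted p = 0.00123) and Tef (0.0144), the period gene Per3 (0.0144) and the repressor gene Nr1d1 (0.0108). Dbp averaged 23.1 ± 1.09, 76.9 ± 6.46, 30 ± 14.8 and 12.3 ± 4.83 CPM at ZT4, ZT10, ZT16 and ZT23 (SD, n = 2 each), and Nr1d1 averaged 192 ± 31, 239 ± 59.3, 94.6 ± 39.3 and 88.8 ± 17.8 CPM. A cosinor with a period of 24 hours put the peak of Nr1d1 at 7.71 ± 0.68 hours (SE), Nr1d2 at 8.15 ± 0.90, Dbp at 10.36 ± 0.64, Per3 at 11.99 ± 0.94, Tef at 12.13 ± 1.33 and Per2 at 13.17 ± 1.55. The transcriptional activator genes Arntl and Clock did not pass adjusted over the list alone and averaged between 35.0 and 45.1 CPM and between 30.3 and 39.7 CPM over the 4 times. All 5 erythroid genes also passed adjusted over the list alone, with Hbb-b1 at 205 ± 249 CPM at ZT23, but 0 did without ILC3 ZT23 replicate 2 (the other 24 lists had 0).

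Over all genes, edgeR's quasi-likelihood test called 0 genes over time in ILC3, with 669 at unadjusted p under 0.05 where chance gives 767. DESeq2 called 28, and limma voom, with and without sample quality weights, called 0. Without ILC3 ZT23 replicate 1 edgeR called 3, Hba-a1, Hba-a2 and Hbb-b1. Without ILC3 ZT4 replicate 2, 24 of 28 epithelial genes and 7 of 26 NF-kB genes passed adjusted over their lists alone, and without ILC3 ZT23 replicate 1, 18 of 43 genes of oxidative phosphorylation did, while the other lists at 0 gained at most 5 members. The count of 4 core clock genes became 1 without ILC3 ZT10 replicate 1 and 7 without ILC2 ZT23 replicate 1 or replicate 2.

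In ILC2, 4 core clock genes changed over time adjusted over the list alone, Tef (adjusted p = 0.00167), Dbp (0.00256), Per2 (0.00348) and Nr1d2 (0.0423). Dbp averaged 29.2 ± 1.77, 53.3 ± 2.64 and 9.77 ± 2.40 CPM at ZT4, ZT10 and ZT23 and 20.2 CPM in the ZT16 library, and Tef averaged 45.3 ± 0.649, 107 ± 4.78 and 27.5 ± 0.0816 CPM, with 61.8 CPM at ZT16. Per2, a repressor of the feedback loop, averaged 10.5 ± 0.424, 32.2 ± 1.58 and 6.05 ± 3.40 CPM, with 22.9 CPM at ZT16. The cosinor peaks were at 5.50 ± 0.95 hours for Nr1d1, 7.99 ± 0.88 for Nr1d2, 9.17 ± 0.36 for Dbp, 10.52 ± 0.77 for Per3, 10.89 ± 0.11 for Tef and 11.61 ± 0.78 for Per2. The measured mean of Nr1d1 was highest at ZT10 in both cell types. In either cell type 4 times leave 1 residual degree of freedom among times for the 24 hour shape. Peaks and their SE therefore only describe, and a difference in peak between the cell types was not tested. Among cholesterol genes 6 of 24 passed adjusted over the list alone (among them Nsdhl, Msmo1, Mvk, Idi1 and Fdps, each with adjusted p = 0.0373). None did without either ILC2 ZT10 library, ILC2 ZT23 replicate 1 or any of the ILC3 libraries of ZT10, ZT16 and ZT23. The other 24 lists had 0 members adjusted over the list alone. Without ILC2 ZT4 replicate 2, 3 myeloid, 3 immediate-early and 2 stromal genes passed, without ILC2 ZT10 replicate 1, 4 myeloid genes did, and without either ILC3 ZT23 library 2 erythroid genes did, while the other gains were of 1 gene each.

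Over all genes, edgeR called 0 genes over time in ILC2, with 516 at unadjusted p under 0.05. DESeq2 called 24, among them Tef, Dbp and Per2, and limma voom called 0.

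**Figure D3:**
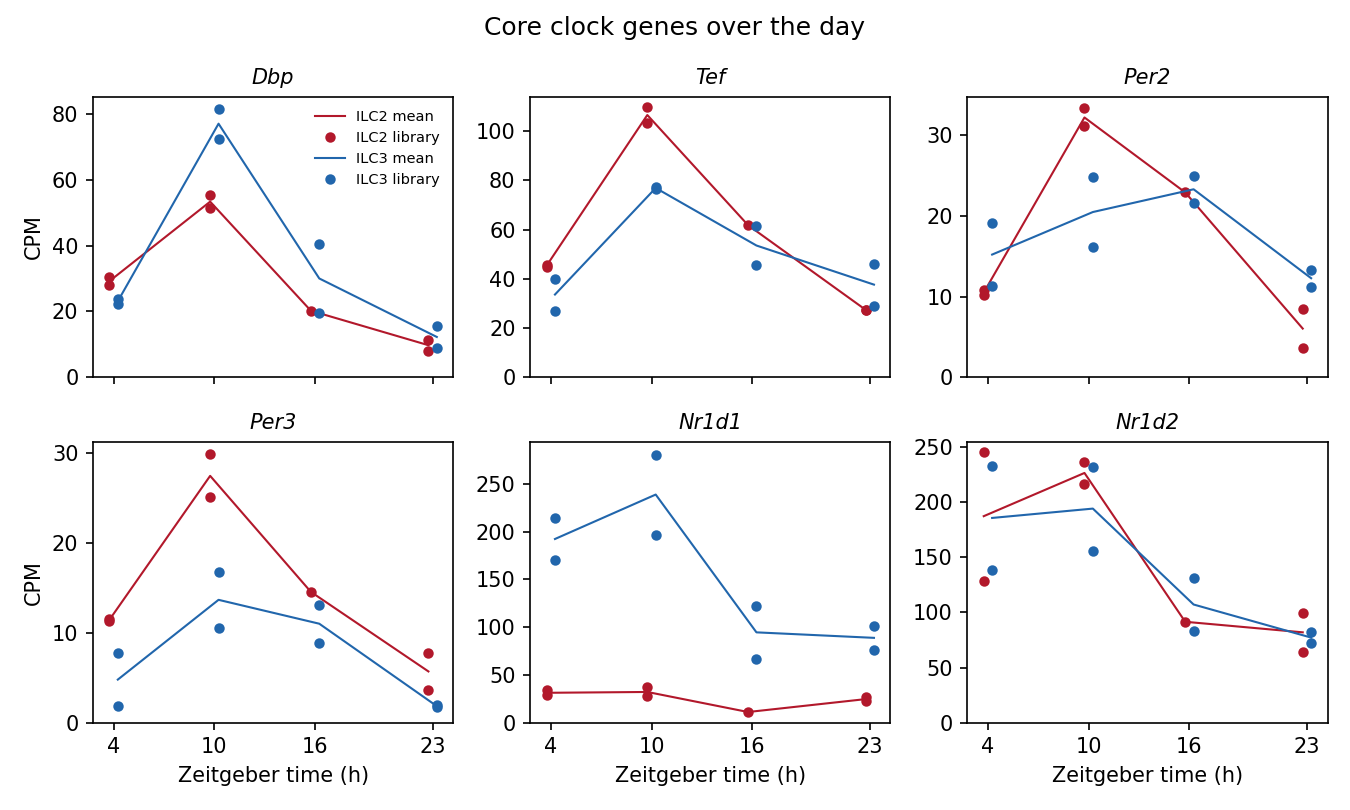
CPM of 6 core clock genes against zeitgeber time in hours, with each point a library and lines joining the group means of ILC2 (red) and ILC3 (blue). Dbp was highest at ZT10 in both cell types, at 53.3 CPM in ILC2 and 76.9 CPM in ILC3, and lowest at ZT23, at 9.77 and 12.3 CPM.

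Whether the time course differs between the cell types was tested as an interaction. No core clock gene passed, and Per2, Nr1d1 and Tef had the smallest values adjusted over the list alone (0.73 each). Of the 26 lists only the erythroid genes had members passing adjusted over the list alone, 4 of 5 (Hba-a1, Hba-a2, Hbb-b1 and Hbb-bs, each with adjusted p = 0.0116). None of these passed without ILC3 ZT23 replicate 2, ILC2 ZT23 replicate 1 or ILC2 ZT23 replicate 2. Without ILC3 ZT4 replicate 2, 2 cytotoxic and type 1, 2 myeloid and 1 immediate-early genes passed, and 1 class II gene did without ILC2 ZT10 replicate 1, 1 heat shock gene without ILC2 ZT23 replicate 1 and 1 interferon-response gene without ILC2 ZT23 replicate 2. Over all genes edgeR called 0, with 307 at unadjusted p under 0.05. DESeq2 called 2, the antiviral receptor gene Tlr3 and the interferon-induced gene Ifitm1, named after their values were seen, and limma voom called 0. In simulated counts with 200 changed genes this interaction test called 0% of 2-fold and 0% of 4-fold changes over all genes, and 70% of the 4-fold changes had an unadjusted p under 0.05.

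At ZT23 compared with ZT10 in ILC3, 19 of 21 core clock genes had a negative log2 fold change, and 8 were lower adjusted over the list alone. Dbp fell by 2.64 on the log2 scale (SE 0.38; adjusted p over the list = 0.000275), Per3 by 2.90 (0.62; 0.00476), Hlf by 1.82 (0.48; 0.0102), and Nr1d1 by 1.43 (0.32; 0.00476). Nr1d2 fell by 1.33 (0.38; 0.0137), Cry2 by 1.31 (0.48; 0.0472), Per1 by 1.08 (0.31; 0.0137) and Tef by 1.03 (0.27; 0.0102). The list passed camera (median -0.69; adjusted p = 2.17e-09; adjusted p = 0.333 with an estimated correlation). In 17 of 21 genes both ZT10 libraries lay above both ZT23 libraries. Chance gives 16.7% for each gene, but genes measured in the same libraries are not independent, so this count only describes. Cholesterol genes were higher at ZT23 as a list (median 0.43, camera adjusted p = 4e-06, adjusted p = 0.333 with an estimated correlation), with 0 of 24 adjusted over the list alone and Msmo1 at 0.91 ± 0.24 (adjusted p over the list = 0.0678). Tspan4 (-1.99 ± 0.43) was the clock output gene that passed adjusted over the list alone, and it did not pass without ILC3 ZT10 replicate 2 or ILC3 ZT23 replicate 2.

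Markers of other cells and signs of library quality moved with this contrast. Epithelial genes (median 2.93, camera adjusted p = 5.97e-11, adjusted p = 0.572 with an estimated correlation) and genes of oxidative phosphorylation (median 0.66, adjusted p = 4.9e-16, adjusted p = 0.572 with an estimated correlation) were higher at ZT23, each with 0 adjusted over the list alone. Without ILC3 ZT23 replicate 2 their medians were 1.07 and 0.20. Without either ILC3 ZT4 library 13 epithelial genes passed adjusted over the list alone, and without ILC3 ZT23 replicate 1 37 of the 43 genes of oxidative phosphorylation did. ILC3 ZT23 replicate 2 had 11.1% of its counts in mitochondrial genes. B cell and plasma cell genes passed for 5 of 15 adjusted over the list alone, with Jchain at 3.27 ± 0.93, and erythroid genes for 4 of 5, with Hbb-b1 at 2.65 ± 0.82. Without ILC3 ZT23 replicate 2, 0 of either passed and the erythroid median turned from 2.65 to -0.38. Without ILC3 ZT10 replicate 1 or replicate 2, too, 0 of either list passed, and without ILC3 ZT23 replicate 1 9 of the 15 B cell and plasma cell genes did.

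Over all genes edgeR called 0 at ZT23 compared with ZT10 in ILC3, with 1253 at unadjusted p under 0.05 and Dbp at the smallest adjusted p, 0.201. DESeq2 called 24, 13 higher and 11 lower, and limma voom 0. The 8 clock genes adjusted over the list alone became 1 without ILC3 ZT10 replicate 1 and 2 without ILC3 ZT23 replicate 2. With Jchain as a covariate, added after the data were seen, 1 of the 8 passed, Per3 at -5.06 ± 0.97. The other 7 lost the call, with Dbp going from -2.64 ± 0.38 to -2.28 ± 0.74 (adjusted p over the list = 0.12) and Nr1d1 from -1.43 ± 0.32 to -0.95 ± 0.65 (0.815). The calls ended because the SE grew (median 0.38 before and 0.683 after) and, in all of the 7 but Tef, the fold became smaller; a share of 0.776 of the variance of Jchain among ILC3 libraries lay between times. Of 15 lists that passed camera 0 passed with an estimated correlation and 0 passed fry, and 4 kept the call without each library in turn: the core clock, cholesterol, epithelial and oxidative phosphorylation lists.

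At ZT23 compared with ZT10 in ILC2, all 24 genes of cholesterol synthesis and uptake had a positive log2 fold change, and 16 passed adjusted over the list alone. The enzyme genes Fdps (1.44 ± 0.34), Idi1 (1.27 ± 0.30), Nsdhl (1.16 ± 0.27) and Msmo1 (1.08 ± 0.25) were among those with the smallest adjusted p over the list, 0.00623 each. Sqle (1.00 ± 0.29) and Hmgcs1 (1.00 ± 0.31) also passed. Fdps averaged 46.1 ± 0.134 CPM at ZT10 and 125 ± 61.8 at ZT23. In 20 of 24 genes both ZT23 libraries lay above both ZT10 libraries, and in ILC3 this held for 18 of 24. Chance gives 16.7% for each gene, but genes of a list measured in the same libraries are not independent, so these counts only describe. The list passed camera (median 0.77; adjusted p = 2.18e-23) and was the list that also passed with an estimated correlation (adjusted p = 0.0144) and by fry (adjusted p = 0.0226).

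Of 21 core clock genes 15 had a negative log2 fold change and 6 a positive one, and 5 passed adjusted over the list alone. Tef fell by 1.96 on the log2 scale (SE 0.28; adjusted p over the list = 0.000255), Dbp by 2.46 (0.38; 0.000308), Per2 by 2.43 (0.44; 0.00081), Per3 by 2.28 (0.60; 0.0106) and Nr1d2 by 1.47 (0.39; 0.0106). The list passed camera (median -0.31; adjusted p = 1.44e-09; adjusted p = 0.314 with an estimated correlation), and 3 genes passed without ILC2 ZT10 replicate 1. Across the 21 clock genes the log2 fold changes from ZT10 to ZT23 of ILC2 and ILC3, which share no libraries, had Pearson's r = 0.729 and Spearman's rho = 0.784, where genes are not independent replicates, and 17 of 21 had the same sign. Over 9214 expressed genes r was 0.399 and 61.1% had the same sign. Cells of 6 mice were pooled per time before the sort, so ILC2 and ILC3 of a time may come from the same mice. The agreement can then hold differences between pools as well as time.

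Over all genes edgeR called 0 at ZT23 compared with ZT10 in ILC2, with 445 at unadjusted p under 0.05 and Tef at the smallest adjusted p, 0.186. DESeq2 called 5, Tef, Dbp, Per2, Gcg and Ifitm1, named after their values were seen, and limma voom 0. The count of 16 cholesterol genes became 0 without ILC2 ZT10 replicate 2 or ILC2 ZT23 replicate 1, 6 without ILC2 ZT10 replicate 1 and 11 without ILC2 ZT23 replicate 2, and the list's adjusted p with an estimated correlation became 0.103, 0.0795, 0.0612 and 0.0421. Markers of other cells moved in the same contrast. Epithelial genes (median 1.03, camera adjusted p = 0.00183, adjusted p = 0.694 with an estimated correlation) and B cell and plasma cell genes (median 0.80, camera adjusted p = 0.00261, adjusted p = 0.551 with an estimated correlation) were higher at ZT23. Myeloid, dendritic and mast cell genes were higher (median 0.30, camera adjusted p = 4.19e-06, adjusted p = 0.535 with an estimated correlation). T cell genes (median -0.54, camera adjusted p = 5.51e-05, adjusted p = 0.578 with an estimated correlation) and cytotoxic and type 1 genes (median -0.21, or -0.08 with genes at 0 counts held at their bound, camera adjusted p = 0.0245, adjusted p = 0.694 with an estimated correlation) were lower. Jchain took 15.7% of the counts of ILC2 ZT23 replicate 1 and 1.85% of replicate 2, and without replicate 1 the B cell and plasma cell median was -0.43. Of the other 12 lists that passed camera each lost the call or turned its direction without at least 1 library: 11 of them without ILC2 ZT10 replicate 2, 7 without ILC2 ZT23 replicate 1, 4 without ILC2 ZT23 replicate 2 and 1 without ILC2 ZT10 replicate 1.

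**Figure D4:**
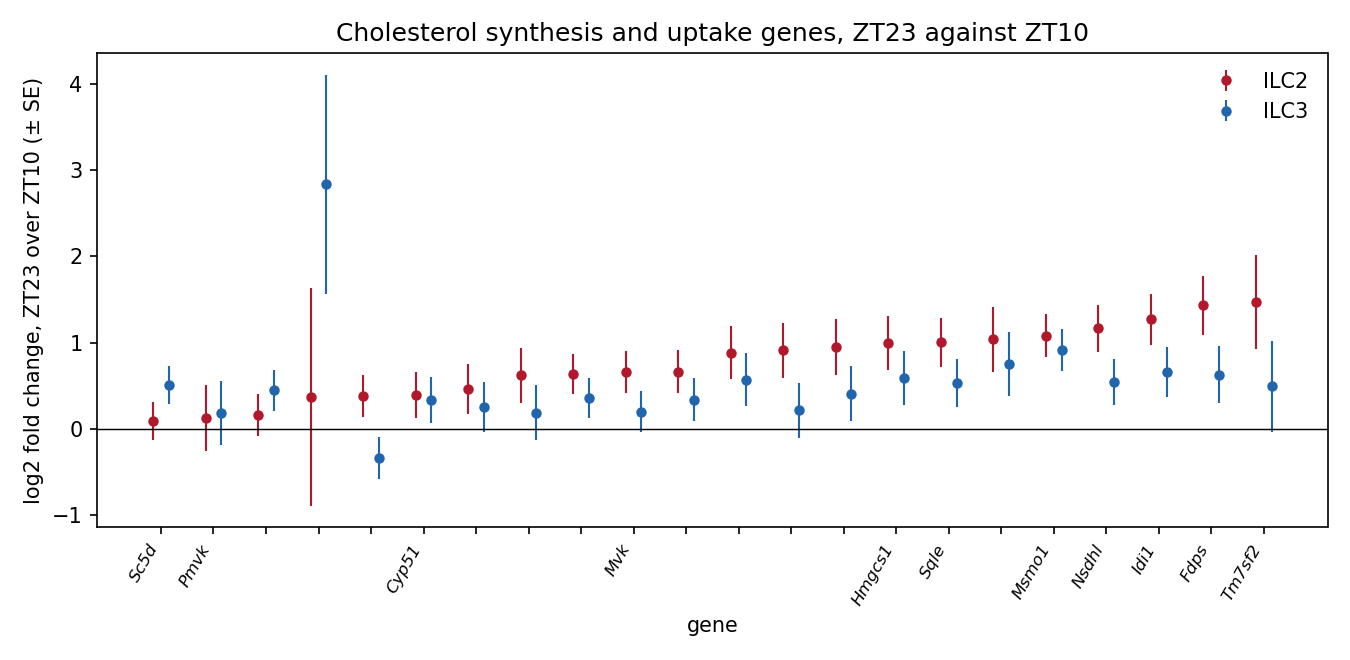
Log2 fold change of ZT23 over ZT10 for 22 of the 24 cholesterol synthesis and uptake genes, points being the fitted values in ILC2 (red) and ILC3 (blue) and bars their SE. Every value was positive in ILC2, from 0.09 for Sc5d to 1.47 for Tm7sf2, and 1 value shown was negative in ILC3.

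At ZT16 compared with ZT4, no core clock gene passed in either cell type. Without ILC3 ZT16 replicate 1, 1 passed adjusted over the list alone in each cell type, and without ILC3 ZT16 replicate 2, 1 did in ILC2. Nr1d1 was at -1.02 ± 0.31 in ILC3 (adjusted p over the list = 0.118) and -1.50 ± 0.42 in ILC2 (0.0797), and Cry1 was at 0.76 ± 0.25 in ILC3 (0.118). In ILC3 the collagen genes Col3a1 (-8.73 ± 2.48) and Col1a2 (-6.43 ± 1.77) fell adjusted over the list of stromal genes alone (0.0329 each). Both were lost without ILC3 ZT4 replicate 2, either ILC3 ZT16 library or either ILC2 ZT23 library, and without ILC3 ZT4 replicate 1 the count was 4. In ILC2 heat shock genes were higher in the ZT16 library than at ZT4 as a list (median 0.58, camera adjusted p = 0.000654, adjusted p = 0.828 with an estimated correlation), a call that held without each of the other 14 libraries, while the ZT16 library, on which it rests, cannot be left out. Hsph1 (1.64 ± 0.42, adjusted p over the list = 0.032) and the mast cell gene Cpa3 (2.83 ± 0.68; 0.0308) passed adjusted over their lists alone, and with 1 library at ZT16 both rest on that library varying like the other groups. Hsph1 did not pass without either ILC2 ZT4 library, ILC2 ZT10 replicate 1 or any of the ILC3 libraries of ZT10 and ZT16, and Cpa3 did not without ILC2 ZT4 replicate 1, either ILC2 ZT10 library or either ILC3 ZT10 library.

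Over all genes edgeR called 0 at ZT16 compared with ZT4 in ILC3, with 511 at unadjusted p under 0.05, and 0 in ILC2, with 724. DESeq2 called 2 in ILC3 (Col1a2 and Kantr, 1 each way) and 4 in ILC2 (Selenon, Gata2, Il1a and Gkn3, 1 higher and 3 lower), named after their values were seen, and limma voom called 0 in both. In ILC3 all 12 lists that passed camera lost the call or turned its direction without at least 1 library. Of these 8 did so without ILC3 ZT4 replicate 1 and 4 without ILC3 ZT4 replicate 2. Without ILC3 ZT16 replicate 1 6 did, and without ILC3 ZT16 replicate 2 3 did. Without ILC3 ZT4 replicate 2, 10 T cell, 8 NF-kB, 8 clock output and 6 class II genes passed adjusted over their lists alone, where 0 did with all libraries. In ILC2 the other 3 of 4 lists lost the camera call or turned its direction without ILC2 ZT4 replicate 1. None of the lists passed with an estimated correlation or by fry in either cell type.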

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

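The tests of plasma cell, plasmacytoid dendritic cell and macrophage markers below were chosen after the results were seen. Predictions for the cholesterol genes in ILC2, the clock genes and the cell type splits were written before the results of those tests. The Jchain covariate used for the cholesterol genes was itself added after the data were seen. No prediction was written for the splits of the cholesterol genes in ILC3. Hba-a1, Hba-a2, Hbb-b1 and Hbb-bs stood out because their time courses differed between the cell types, each with adjusted p = 0.0116 over the erythroid list alone. Hbb-b1 averaged 205 ± 249 CPM in ILC3 at ZT23 and 9.94 ± 0.236 in ILC2 at ZT23 (SD, n = 2 each). Hemoglobin RNA is made by red cell precursors, and ILC3 ZT23 replicate 2, which carried most of it, also had 11.1% of its counts in mitochondrial genes, where the other libraries had 3.92% to 6.54%. Without that library 0 of the 4 genes passed.

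The plasma cell genes varied together between the ILC2 libraries, where 11 plasma cell markers had a median r of 0.938 with Jchain (rho 0.929, exact permutation p = 0.000992, 0.858 without the 2 farthest libraries, Benjamini-Hochberg p over 60 relations 0.0595). The ILC2 signature had a median r of -0.702 with Jchain (rho -0.661, exact permutation p = 0.0131, -0.412 without the 2 farthest, Benjamini-Hochberg p over 60 relations 0.0997), and the ILC3 signature fell in the same way (-0.65, rho -0.625, exact permutation p = 0.00516, -0.431 without the 2 farthest, Benjamini-Hochberg p over 60 relations 0.0997). RNA from plasma cells, in cells sorted with the ILC2 or free, may explain the variation. Expression by the ILC2 themselves stays open, as neither test passed over all relations. The fall of the ILC3 signature cannot decide between them, as added RNA of other cells would lower both signatures, and the lists share Lif and Csf2. Of the 12 plasma cell markers, 5 were held by another list and 8 also reached 10 CPM in ILC3, and Jchain, Txndc5 and Xbp1 averaged 78580, 2993 and 2109 CPM in ILC2, and a sort that excludes cells positive for CD138 would remove such cells, but the gates were not given in the sources used here.

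Across the 7 ILC2 libraries 14 other markers of plasmacytoid dendritic cells had a median r of 0.844 with Siglech (rho 0.786, exact permutation p = 0.0113, 0.74 without the 2 farthest, Benjamini-Hochberg p over 60 relations 0.0997). Epithelial genes followed Siglech as closely (median r 0.857, rho 0.661, exact permutation p = 0.0286, 0.723 without the 2 farthest, Benjamini-Hochberg p over 60 relations 0.172). The ratio of Jchain to Siglech ranged 12.2-fold over these libraries, against at most 4.46-fold for the ratios of Jchain to the other plasma cell markers, so cells that hold both RNAs in fixed amounts do not account for it. All 15 markers reached 10 CPM in ILC2 and 7 did in ILC3, 1 was held by another list, and Ly6d, Irf8 and Siglech averaged 402, 332.8 and 298.4 CPM in ILC2, although Ly6d was highest and lowest in the same libraries as Jchain (810.6 and 182.8 CPM, ZT23 replicates 1 and 2). RNA from plasmacytoid dendritic cells could be present, alone or with RNA of other cells that varied alike, and a sort that excludes cells positive for Siglec-H or B220 would remove them.

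The rise of cholesterol genes at ZT23 in ILC2 was tested against plasma cell RNA, a single library and chance. With Jchain as a covariate the median log2 fold change was 0.6617, and 13 of the 16 genes that passed had a smaller fold. Without each of the 4 ILC2 libraries of ZT10 and ZT23 the median was at least 0.6449. Neither plasma cell RNA that follows Jchain nor 1 library thus accounts for the direction by itself. RNA of other cells was not adjusted for. The list had a median r of 0.303 with Siglech (exact permutation p = 0.445) and a rho of 0.661 (exact permutation p = 0.027) across the ILC2 libraries. Of all ways to split the 7 libraries into groups of these sizes, 19 gave a share of variance between times as large as the real one (0.6422, highest other 0.7574, permutation p = 0.181). Chance therefore cannot be excluded for the list over the 4 times in ILC2. In ILC3 2 splits were as large, the real one among them (0.6369, highest other 0.6382, permutation p = 0.019, Benjamini-Hochberg p over 62 tests 0.393). That test was not named in advance and did not pass over the 62 tests, so chance cannot be excluded there either.

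Macrophage genes varied over time in ILC3, with 12 of 15 lowest at ZT10, and C1qa averaged 191.2, 50.18, 125.2 and 121.8 CPM at ZT4, ZT10, ZT16 and ZT23. The real grouping was the 1 split with so large a share of variance between times (0.8249, highest other 0.756, permutation p = 0.00952). This is the smallest p these splits can give, so the Benjamini-Hochberg p over 62 tests of 0.295 could hardly pass. The list was also written after the results were seen, so the splits cannot exclude chance for it. Of the lists fixed before the data were examined, the unfolded protein response had the same permutation p of 0.00952 in ILC3 (0.5645, highest other 0.5644, Benjamini-Hochberg p over 62 tests 0.295) and the myeloid list 0.0381 (Benjamini-Hochberg p 0.472). More macrophage RNA in some pools than in others could give the same pattern as a change within ILC3, as 13 of the 15 markers reached 10 CPM in ILC3, 8 were held by another list, and Lyz2, Ctss and Apoe averaged 993.4, 678.8 and 606.9 CPM. A sort that excludes cells positive for F4/80 or CD64 would remove macrophages.

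For core clock genes 15 splits in ILC2 were as large as the real one (0.5935, highest other 0.7473, permutation p = 0.143), so chance is not excluded for the list. In ILC3 3 splits were, the real one among them (0.6272, highest other 0.6553, permutation p = 0.0286, Benjamini-Hochberg p over 62 tests 0.443). The list, named in advance, was under 0.05 taken alone but did not pass over the 62 tests, so chance is not excluded. The splits also cannot tell time from a difference between pools, as the 2 libraries of a time may share a pool. For cell type a 2-group fit was run on 100 splits drawn from 6435, and only the real one called as many genes (4306, highest other 817). Every other split mixed the cell types, which adds their difference to the spread and lowers the calls. The count is thus larger than random splits of these libraries gave, but the splits cannot tell cell type from batch.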

How the results depend on the processing

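Which of these results depended on the processing was followed over the alternatives, and where a value moved the cause was not tested unless fewer libraries or a stricter threshold gives it. The number of genes differing between the cell types was 1374 with glmTreat, 2413 at adjusted p under 0.01 and 1835 with a replicate block and without the ILC2 ZT16 library together, and between 3270 (without ILC3 ZT16 replicate 2) and 4214 (without ILC2 ZT4 replicate 2) without each library. The 30 genes named for cell type kept direction and call in 810 of 810 values. DESeq2 called 28 genes over time in ILC3, 24 over time in ILC2, 2 in the interaction, 2 and 24 in ILC3 at ZT16 minus ZT4 and ZT23 minus ZT10, and 4 and 5 in ILC2. Without a low-count filter 1 gene was called in ILC3 at ZT23 minus ZT10 and 2 in ILC2. Over time in ILC3 the count ran from 0 to 3 without each library.

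For core clock genes over time in ILC3 the count of 4 was 7 with DESeq2, with the cosinor, and with the replicate block without the ILC2 ZT16 library, and 1 at adjusted p under 0.01, with only ILC3 libraries and with Jchain as a covariate, and ran from 1 to 7 without each library. Over time in ILC2 it ran from 3 to 5 without each library. At ZT23 minus ZT10 in ILC3 the count of 8 was 3 at adjusted p under 0.01, 1 with the Jchain covariate and 2 without the 3 libraries that stand apart, and ran from 1 to 8 without each library. In ILC2 the count of 5 was 3 at adjusted p under 0.01 and ran from 3 to 6. For cholesterol genes at ZT23 minus ZT10 in ILC2 the count of 16 was 6 with library size only, 5 with glmTreat, 5 at adjusted p under 0.01 and 8 with only ILC2 libraries, and ran from 0 to 16. Over time in ILC2 the count of 6 was 0 with voom, library size only, adjusted p under 0.01 and only ILC2 libraries, 2 with quality weights and 11 with the cosinor, and ran from 0 to 9. For erythroid genes in the interaction the count of 4 was 0 with voom, quality weights, adjusted p under 0.01, the cosinor and without the 3 libraries that stand apart, and ran from 0 to 5. Of 13, 12, 15, 4 and 14 lists that passed camera for cell type, ILC3 ZT16 minus ZT4, ILC3 ZT23 minus ZT10, ILC2 ZT16 minus ZT4 and ILC2 ZT23 minus ZT10, 0, 0, 0, 0 and 1 passed with an estimated correlation, and the last 4 had 0, 0, 0 and 1 by fry.

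Peak times ran from 8.76 (without ILC2 ZT16) to 9.343 hours for Dbp in ILC2, 9.83 to 11.14 for Dbp in ILC3, 4.595 to 7.29 (without ILC2 ZT16) for Nr1d1 in ILC2, 7.225 to 8.404 for Nr1d1 in ILC3 and 10.83 to 11.06 for Tef in ILC2. Correlations between groups by replicate number passed 0.1 in 0 of 3 pairs of times in ILC2 and 2 of 6 in ILC3. The highest was 0.417, between ILC3 ZT4 and ZT23. With so few libraries they cannot settle whether replicate numbers pair samples. ILC2 ZT16 minus ZT4 has no replicate-block value because ZT16 is left out. Of the 30 cell type genes, the 16 cholesterol genes of ILC2 and the 5 and 8 clock genes of ILC2 and ILC3 at ZT23 minus ZT10, 0 reversed direction.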

Other observations

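Several tests below were chosen after the result was seen. In the ILC3 libraries cholesterol genes also had both ZT23 libraries above both ZT10 libraries in 18 of 24 genes. Their log2 fold changes had the same sign as in ILC2 in 23 of 24 genes but hardly followed them in size (Pearson's r = 0.0397, Spearman's rho = 0.456 across 24 genes, which are not independent replicates). From ZT4 to ZT16 the clock genes of ILC2 and ILC3 had r = 0.752 and rho = 0.79 across 21 genes, and 17 had the same sign.

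Genes with r above 0.9 to Jchain across the ILC2 libraries were 176 of the 1839 genes higher in ILC2 (9.57%), against 0.431% of the genes higher in ILC3 and 1.07% of the genes not called. For Siglech the shares were 2.39% of the genes higher in ILC2, 1.51% of those higher in ILC3 and 3.22% of those not called. Genes higher in ILC2 thus followed Siglech no more often than genes not called. Mature B cell markers did not follow Jchain (median r = -0.103, rho -0.0893, exact permutation p = 0.696, 0.436 without the 2 farthest, Benjamini-Hochberg p over 60 relations 0.831).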
